A study of Sphingobium sp. SYK-6 with 6 samples.

How the data were processed

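Total RNA of Sphingobium sp. SYK-6 was measured on spotted whole-genome microarrays after growth in a sucrose, glutamate, proline and methionine medium (SEMP, as the labels abbreviate it). Per the labels, cultures were then kept for 2 h with 2 mM vanillate, for 6 h with 2 mM DCA, or for 2 h without substrate, and were grown and harvested independently. The labels do not spell out DCA. Per the labels, each of the 6 samples (3 with vanillate, 3 with DCA) is a 2-colour array of treated RNA against SEMP RNA, with the dyes exchanged in replicate 3.

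The deposited scanner files hold the intensity of each spot and of its local background on a linear scale, quantified with software version 6.1.0 and not yet background-subtracted, per the file headers. Per the file headers, all scans were made at 635 nm on separate arrays that carried RNA-derived target in Cy5 and genomic DNA in Cy3; the genomic DNA channel was not analysed here. The deposited pairs were therefore combined from separate scans, and the files given as Cy3 are 3 SEMP scans with identical values in both groups, which leaves 9 distinct scans. The headers name the DCA scans by another abbreviation, PC. In replicate 3 of both groups the labels and the headers disagree on which file of the pair holds the treated RNA. Turned as labelled, replicate 3 correlated with the other replicates of its group at r = -0.78 and -0.84 for vanillate and -0.87 and -0.85 for DCA, across genes; turned by its headers, the same values are above 0. The file labelled as treated in replicate 3 is 1 scan deposited in both groups, so the labels cannot hold in both. By a rule set before the data were examined, replicate 3 was then left out of the fit, with both directions as alternatives. The design set before the data were examined assumed both dyes on an array; it was kept, and loess acts here on a pair of separate scans.

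The deposited table of processed values holds log2 ratios whose method is not given in the sources used here. Set against the scans by quantiles, its columns gave r from 0.993 to 1.00 for log2 of treated over control, with replicate 3 turned by its headers, and r from 0.967 to 0.997 for the opposite sign. The first was higher in each column but barely for DCA replicate 2 (0.998 against 0.997), so this direction is likely, not settled. Within the table, replicate 3 correlated with the other replicates of its group at 0.763 to 0.814. The scale has slopes from 1.14 to 1.31. The column medians are 0.00446, 2.4e-04 and -0.00327 for vanillate and -0.0096, -0.00661 and 2.85e-04 for DCA. Its rows carry no gene names and do not follow the spot order (r = 0.03), so it served only as an alternative for counts and similarity. Of the columns with per-sample values, 0 were left unmapped.

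Background was corrected with normexp (offset 50) and log ratios were normalised by loess within each pair, with the 218 control spots left out of the curve and the tests. The 5542 gene spots gave 4299 genes, of which 3074 have 1 spot, 1207 have 2 and 18 have 3; spots of a gene were averaged. Names, products and locus tags are those of the array files: 3912 loci on the chromosome, 150 on the plasmid and 237 from draft contigs, with a symbol for 860. No reference genome was used here, so no coordinates are given. The offset makes folds of dim genes smaller than they are. Fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on replicates 1 and 2 of each group, in 1 model with a mean per group, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model has 2 residual and 3.54 prior degrees of freedom. Both residual differences, vanillate 1 minus 2 and DCA 1 minus 2, hold the same control scans and correlated across genes at r = 0.39. They are not independent estimates of the spread, so the adjusted p may be too small. Every ± is the standard error of the log2 change, with n = 2 arrays.

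The fit was tested on simulated data for vanillate against control over 4299 genes: of 50 genes each with a true log2 change of 0.5, 1, 2 and 3, it called 8%, 58%, 90% and 90%, and 2 of 4099 unchanged genes. A true log2 change of 2 came out at a median of 1.32. On the same simulated data, the fit of 9 scans as separate channels called 30%, 98%, 96% and 98%, and 14 of 4099 unchanged genes. Simulated spot noise was a fraction of the spread between control scans, joined by an assumed spread per gene. No batch difference between treated and control scans was simulated, so these rates may not hold for the real scans. The number of arrays limits the precision. Median spot signal ran from 74.5 (vanillate replicate 3) to 219 (DCA replicate 2) over local backgrounds of 37 to 55, and 0 spots were saturated. Genes whose spots were all marked empty on every scan of a group in the fit numbered 66 for SEMP, 109 for vanillate and 88 for DCA. The threshold for marking a spot empty differed between scans, so counts built on these marks are not on a common scale across groups. Of the called genes, 2 with vanillate and 6 with DCA were not above background in 1 of the groups; none of them is named.

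Of 22 gene lists fixed by symbol, product or locus tag before the data were examined, 21 had at least 5 members. These were tested with camera (preset correlation 0.01), beside camera with an estimated correlation and fry. With an estimated correlation, camera tests on the 2 residual degrees of freedom of the fit and has little power. A list call lost there is therefore not by itself a sign that its members are correlated. The estimated correlation was 0.708 for the TonB-ExbB-ExbD list and 0.268 for the flagellar list, so correlation may add to the loss there. Genes were named by a rule also fixed then: the 8 largest rises and falls per treatment among called genes with the same direction on every array of the fit, up to 3 called members of each list by adjusted p, all members of the vanillate and phenylcoumaran lists found by symbol or tag up to 25, and for DCA against vanillate the 5 largest differences each way. Genes and differences outside the rule are said to be so where they are given.

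Same-numbered arrays share a control scan. Their ratios deviated together in all 3 pairs (r = 0.41, 0.37 and 0.36), while the treated scans alone gave 0.05, 0.01 and 0.15, so the numbers pair the ratios through the control scan. The image folders named in the headers carry 1 number for the SEMP scans and another for the vanillate and DCA scans. These numbers were read here as hybridisation sets. Per the file headers, the SEMP and DCA scans were quantified on 1 day and the vanillate scans on another. Alternatives changed the background correction, the normalisation, the filter on dim genes, the spot summary, the handling of replicate 3, the model and the samples.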

Results

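Gene expression of Sphingobium sp. SYK-6, a soil bacterium known for growth on lignin-derived aromatic compounds, was compared between cultures given vanillate for 2 h, DCA for 6 h (both 2 mM) or no substrate for 2 h. Each group has 3 scans. The fits rest on replicates 1 and 2, by a rule set beforehand for labels of replicate 3 that the scans contradict. Spots marked empty made up 3.05% to 3.36% of gene spots on the control scans, 5.77%, 6.62% and 14.2% with vanillate and 6.01%, 4.35% and 4.89% with DCA. The threshold for marking a spot empty was 2.2 for the control scans, 1.7, 1.7 and 1.5 with vanillate and 3.0, 3.0 and 2.2 with DCA. These shares are therefore not on a common scale.

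The first comparison asks which genes respond to vanillate, a methoxylated aromatic acid. The largest rise was that of desA (SLG_25000), annotated as syringate O-demethylase, at 4.17 ± 0.12 on the log2 scale, or 18.0-fold (n = 2 arrays, adjusted p = 2.41e-04). The vanillate O-demethylase gene ligM (SLG_12740) rose by 3.03 ± 0.10 (adjusted p = 2.47e-04) and the gallate dioxygenase gene desB (SLG_03330) by 2.53 ± 0.11 (adjusted p = 4.41e-04). A pair of genes annotated as protocatechuate 4,5-dioxygenase subunits, SLG_37520 and SLG_37530, rose by 3.89 ± 0.26 and 3.54 ± 0.20. Genes of a cbb3-type cytochrome c oxidase, a terminal oxidase with high affinity for oxygen, rose alongside: ccoP by 3.88 ± 0.26, ccoQ by 3.43 ± 0.22 and ccoO by 3.39 ± 0.18.

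Of the 18 measured members of the list for vanillate and protocatechuate catabolism, 11 rose and 1 fell with vanillate (12 and 2 adjusted over the list alone). The camera adjusted p was 3.18e-06 (adjusted p = 0.476 with an estimated correlation). The ring-cleavage pathway genes ligB, ligC, ligA (SLG_12510), ligK, ligJ and ligI rose by 2.09 ± 0.17, 1.71 ± 0.11, 1.40 ± 0.11, 1.17 ± 0.13, 1.12 ± 0.10 and 0.84 ± 0.11. Without vanillate replicate 2 the call of ligI ended (0.72, adjusted p = 0.0601). The regulator gene ligR changed by 0.13 ± 0.09 and missed the threshold (adjusted p = 0.368). The list also took in SLG_11790, a DNA ligase that shares the symbol ligA and stood at -0.33 ± 0.10 (adjusted p = 0.0737). It passed with replicate 3 turned as its headers say (-0.38, adjusted p = 0.00822) and with 9 scans (-0.44, adjusted p = 0.00604). In the list for one-carbon and tetrahydrofolate metabolism, 4 of 8 members rose and 2 fell, as also adjusted over the list alone (adjusted p = 0.124); ligH and metF, which act on the methyl groups released by O-demethylation, rose by 1.39 ± 0.14 and 0.95 ± 0.10.

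Of 19 chaperone and heat shock genes, 13 rose and 1 fell with vanillate, as also adjusted over the list alone (adjusted p = 3.22e-06; adjusted p = 0.476 with an estimated correlation). The small heat shock genes SLG_26780 and SLG_32050 rose by 1.98 ± 0.11 and 1.46 ± 0.12 and the chaperonin gene groES (SLG_00810) by 1.72 ± 0.13. The member that fell, SLG_37570, named after its values were seen, is annotated as a copper chaperone, which does not fold proteins; it stood at -0.82 ± 0.10, a call that ended without vanillate replicate 1 (-0.74, adjusted p = 0.0624). In the list for ATP synthase and the respiratory chain, 19 of 48 members rose and 1 fell (21 and 3 adjusted over the list alone; adjusted p = 6.05e-04). That list's call ended with an estimated correlation (adjusted p = 0.476) and with median centring in place of loess (adjusted p = 0.491). The list holds the cbb3 oxidase genes ccoO, ccoP and ccoQ given above, so its call is not separate from their rise. Its mean log2 change was 0.50 and its median 0.28, and it was not tested without these genes. Of 5 genes of the TonB-ExbB-ExbD system, which powers outer membrane uptake, 4 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.00169), exbB (SLG_14440) by 0.93 ± 0.09. Its call ended with an estimated correlation (adjusted p = 0.613) and with median centring (adjusted p = 0.065). Of 43 flagellar and chemotaxis genes, 7 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00562, and adjusted p = 0.726 with an estimated correlation); fry gave 0.136.

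The deepest fall with vanillate was that of SLG_27180, a hypothetical protein gene, at -6.47 ± 0.15, followed by its neighbours SLG_27190, a putative ArsR family regulator, at -4.48 ± 0.16 and metE (SLG_27170), the cobalamin-independent methionine synthase, at -3.89 ± 0.22. Among the 8 deepest falls were also SLG_36760 at -3.42 ± 0.16 and SLG_34550, annotated as an iron complex outer membrane receptor, at -2.66 ± 0.28. SLG_36760 belongs to the list of 73 TonB-dependent receptor genes, of which 5 rose and 6 fell (adjusted p = 0.337), and SLG_08200 of that list rose by 1.22 ± 0.12. The TonB-like gene SLG_34540 stood at -2.51 ± 0.36, a call that ended without vanillate replicate 2 (-1.88, adjusted p = 0.0556).

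In all, 961 of 4299 genes passed the threshold with vanillate, 492 higher and 469 lower, and 223 of them changed at least 2-fold (129 higher, 94 lower). The share of higher calls was 51.2%, but 34.5% with median centring, 46.9% with replicate 3 turned as its headers say, 46.2% with 6 scans as separate channels and 45.7% with 9, so which side had more calls depended on these settings. The count was 330 without vanillate replicate 1, 277 without replicate 2, 1578 with replicate 3 turned as its headers say, 1723 with all 9 scans fitted as separate channels, and 0 in limma with replicate 3 turned as labelled (12 at an unadjusted p under 0.05). Each treated group lies in another hybridisation set than the control, and vanillate on another quantification day, so batch and group cannot be told apart for vanillate against control.

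**Figure D1:**
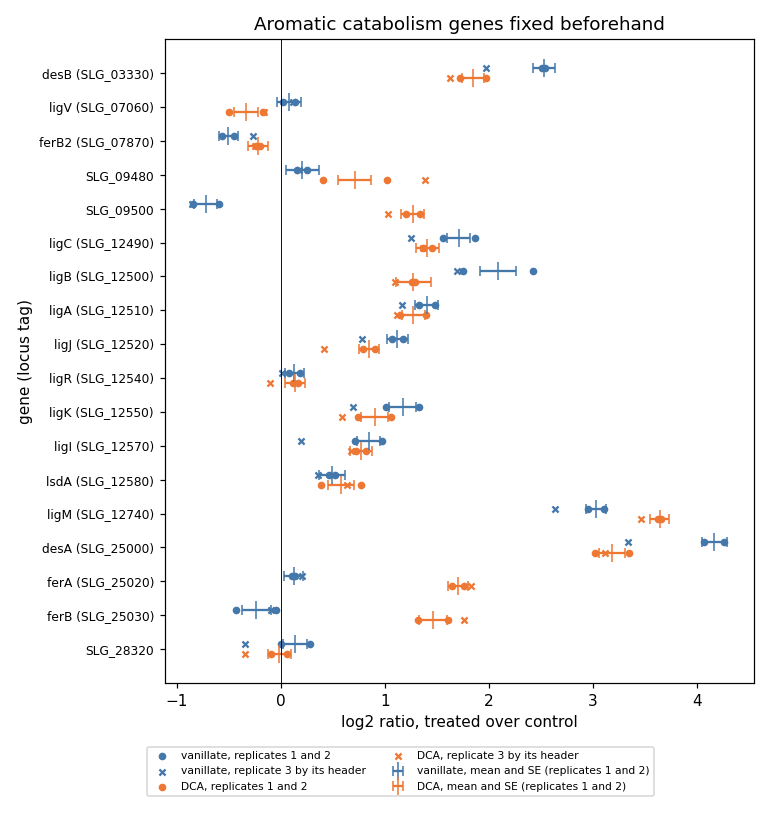
Log2 ratio of treated over control (x axis) for the aromatic catabolism genes named by symbol or tag (y axis), with vanillate in blue and DCA in orange. Dots are replicates 1 and 2, crosses are replicate 3 turned as its headers say, and bars are the mean ± SE of replicates 1 and 2; desA reached 4.17 with vanillate and 3.18 with DCA, while ferA rose by 1.71 with DCA and stood at 0.12 with vanillate.

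With DCA for 6 h, SLG_38040, a hypothetical protein gene, had the largest rise at 3.86 ± 0.09 on the log2 scale, or 14.6-fold (n = 2 arrays, adjusted p = 8.64e-05). Nearby on the chromosome, the TonB-dependent receptor gene SLG_38050 rose by 3.75 ± 0.13, the putative oxidoreductase gene SLG_38070 by 3.17 ± 0.11 and the cytochrome c family gene SLG_38090 by 2.76 ± 0.11. The O-demethylase genes ligM and desA rose by 3.64 ± 0.10 (adjusted p = 9.41e-05) and 3.18 ± 0.12 (adjusted p = 2.13e-04). A formate dehydrogenase subunit gene, SLG_12940, rose by 3.07 ± 0.14 and an efflux outer membrane gene, SLG_34630, by 2.90 ± 0.19.

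Of 18 genes for vanillate and protocatechuate catabolism, 12 rose and 1 fell with DCA, as also adjusted over the list alone (adjusted p = 6.45e-05; adjusted p = 0.522 with an estimated correlation). Among them desB rose by 1.85 ± 0.11, ligC by 1.41 ± 0.11 and ligB by 1.27 ± 0.17. In the list for side chain and ring cleavage of phenylcoumaran-type compounds, 5 of 8 members rose and 0 fell (5 and 1 adjusted over the list alone). The list missed the threshold in camera (adjusted p = 0.084) and passed in fry (adjusted p = 0.0223). In DCA minus vanillate it also missed in camera (adjusted p = 0.0662) and passed in fry (adjusted p = 0.0369). The feruloyl-CoA pathway genes ferA and ferB rose by 1.71 ± 0.09 and 1.46 ± 0.14. SLG_09500 and SLG_09480, both annotated as choline dehydrogenase, were placed in the list as phcD and phcC by locus tags fixed beforehand. SLG_09500 rose by 1.27 ± 0.11 and SLG_09480 by 0.71 ± 0.16, the latter a call that ended without DCA replicate 1 (0.40). Of 8 members with vanillate, 1 rose and 2 fell, as also adjusted over the list alone (adjusted p = 0.943), with a median of 0.10 and a mean of -0.05.

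Ribosomal protein genes rose with DCA in 31 of 56 cases and fell in 1 (32 and 1 adjusted over the list alone; adjusted p = 4.75e-07, and adjusted p = 0.421 with an estimated correlation). The examples rpsA, rplB and rpmC rose by 1.40 ± 0.10, 1.21 ± 0.10 and 1.09 ± 0.09. In the respiratory list, 22 of 48 members rose and 4 fell (24 and 5 adjusted over the list alone; adjusted p = 0.00134, and adjusted p = 0.522 with an estimated correlation). The gene nuoH of NADH dehydrogenase rose by 1.56 ± 0.12, while the cytochrome c oxidase gene ctaE fell by 1.26 ± 0.11. Of 23 aldehyde dehydrogenase genes, 9 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.0287, and adjusted p = 0.697 with an estimated correlation); without DCA replicate 2 the list missed the threshold (adjusted p = 0.0795). Of the 5 genes of the TonB-ExbB-ExbD system 4 rose and 0 fell, as also adjusted over the list alone (adjusted p = 0.0287, and adjusted p = 0.697 with an estimated correlation). That call also ended without DCA replicate 1, where the list mean lay 0.46 above that of other genes, against 0.59 in the main fit. It ended as well with replicate 3 turned as its headers say (adjusted p = 0.0742) and with 9 scans (adjusted p = 0.052). In fry, a separate test that does not compare a list with other genes, this list missed the threshold (adjusted p = 0.0688). Of 19 chaperone genes, 3 rose and 1 fell with DCA (3 and 0 adjusted over the list alone; adjusted p = 0.562). The efflux list had 2 members and was not tested; SLG_23690 rose by 0.86 ± 0.12.

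The deepest falls with DCA were again SLG_27180 at -7.67 ± 0.15, SLG_27190 at -5.08 ± 0.16 and metE at -4.04 ± 0.22, followed by SLG_36760 at -3.49 ± 0.16. The cobA gene (SLG_32270), which acts in siroheme and cobalamin synthesis, fell by 3.17 ± 0.27 and the glutathione S-transferase gene gst (SLG_04120) by 3.02 ± 0.11.

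With DCA 1202 of 4299 genes passed the threshold, 668 higher and 534 lower, and 248 changed at least 2-fold (156 higher, 92 lower). The count was 658 without DCA replicate 1, 369 without replicate 2, 0 in limma with replicate 3 turned as labelled (22 at an unadjusted p under 0.05), and 1564 with all 9 scans fitted as separate channels. The DCA and control scans alone, which share 1 quantification day, gave 1920 when fitted the same way. Lower calls were the more numerous with 6 scans (636 higher, 657 lower), with 9 scans (758 and 806) and within that day (927 and 993). DCA was given for 6 h and the control medium for 2 h, so compound and time are not separated, and neither are treatment and hybridisation set.

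**Figure D2:**
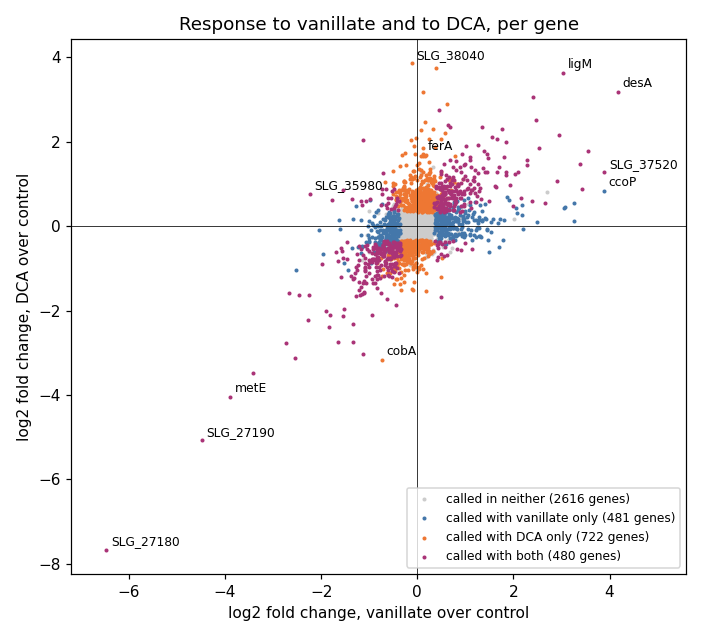
Log2 fold change over control with vanillate (x axis) and with DCA (y axis) for each of the 4299 genes, as means of replicates 1 and 2, coloured by whether the gene was called with vanillate, with DCA, with both or with neither. The named genes with the largest changes are marked; SLG_27180 lies lowest on both axes, at -6.47 and -7.67.

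DCA and vanillate were compared with each other at the same dose, though at 6 h and 2 h. Higher with DCA were SLG_38040 by 3.98 ± 0.13 on the log2 scale (adjusted p = 0.001), SLG_38050 by 3.36 ± 0.18, SLG_09380 by 3.16 ± 0.14, SLG_38070 by 3.04 ± 0.15 and the peptidase gene SLG_35980 by 3.00 ± 0.27 (n = 2 arrays per group). SLG_09380 and SLG_35980 were called in opposite directions, at -1.12 ± 0.10 and -2.24 ± 0.19 with vanillate and 2.04 ± 0.10 and 0.76 ± 0.19 with DCA. These values against control lie outside the rule and were chosen after values were seen. The DCA call of SLG_35980 ended without DCA replicate 2 (0.41, adjusted p = 0.242) and with median centring (0.77, adjusted p = 0.0528). Lower with DCA than with vanillate were SS1C_Con002_0044 at -3.15 ± 0.42, ccoP at -3.05 ± 0.36, SLG_38360 (annotated as FixG) at -2.72 ± 0.35, the OmpW family gene SLG_38320 at -2.62 ± 0.17 and SLG_37520 at -2.61 ± 0.37. Without vanillate replicate 2 the calls of ccoP (-2.80, adjusted p = 0.0592), SLG_37520 (-2.32, adjusted p = 0.0724) and SLG_38360 (-2.72, adjusted p = 0.0637) ended, the last also without vanillate replicate 1 (-2.71, adjusted p = 0.0583).

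The differences of the aromatic catabolism genes given next lie outside the rule for this comparison and were chosen after values were seen. Of these genes, ferA and ferB were higher with DCA by 1.58 ± 0.13 (adjusted p = 0.00854) and 1.70 ± 0.19 (adjusted p = 0.0121), and desA and desB lower, at -0.98 ± 0.17 (adjusted p = 0.0268) and -0.68 ± 0.15 (adjusted p = 0.0493). The call of desA ended without vanillate replicate 1 (-0.88, adjusted p = 0.109), without vanillate replicate 2 (-1.08, adjusted p = 0.0841) and without DCA replicate 2 (-0.82, adjusted p = 0.0976). The call of desB ended without vanillate replicate 1 (-0.70, adjusted p = 0.146) or 2 (-0.67, adjusted p = 0.173) and without DCA replicate 1 (-0.55, adjusted p = 0.164) or 2 (-0.81, adjusted p = 0.0889). Both calls also ended with median centring, at -0.73 (adjusted p = 0.0716) and -0.54 (adjusted p = 0.212). With replicate 3 turned as its headers say they ended at -0.73 (adjusted p = 0.0591) and -0.57 (adjusted p = 0.0571). The call of desB ended as well with no background correction (-0.66, adjusted p = 0.0512) and with the median of spots (-0.56, adjusted p = 0.0973). For ligM the difference was 0.61 (95% confidence interval 0.27 to 0.95, adjusted p = 0.0515). It passed with the replicate block, which takes in the shared control scan (0.61, adjusted p = 0.025; 0.68, adjusted p = 0.00503 with replicate 3). It also passed with no background correction (0.62, adjusted p = 0.0448), with the header direction of replicate 3 (0.68, adjusted p = 0.0129), with 6 and 9 scans (0.43, adjusted p = 0.0131, and 0.40, adjusted p = 0.00274) and within the treated hybridisation set (0.41, adjusted p = 0.00683). For the ring-cleavage gene ligB it was -0.81 (-1.42 to -0.21, adjusted p = 0.1). It passed with the replicate block (-0.81, adjusted p = 0.0436; -0.74, adjusted p = 0.0164 with replicate 3), with the header direction of replicate 3 (-0.74, adjusted p = 0.0328), with 6 and 9 scans (-0.89, adjusted p = 0.0288, and -0.89, adjusted p = 0.00126), within the treated hybridisation set (-0.87, adjusted p = 0.00636) and without vanillate replicate 1 (-1.15, adjusted p = 0.046). Without vanillate replicate 2 it was -0.48 (adjusted p = 0.239). For ligC it was -0.30 (-0.70 to 0.10), which passed with 9 scans (-0.33, adjusted p = 0.0329), and for ligK -0.27 (-0.74 to 0.20). For the protocatechuate dioxygenase gene ligA (SLG_12510) it was -0.13 (-0.52 to 0.26), for ligJ -0.27 (-0.62 to 0.07) and for ligI -0.07 (-0.45 to 0.31), and these also missed the threshold. For ligJ it passed with 6 and 9 scans (-0.38, adjusted p = 0.0389, and -0.46, adjusted p = 0.00641), within the treated hybridisation set (-0.43, adjusted p = 0.0218) and with the block and replicate 3 (-0.30, adjusted p = 0.0479). Of the 18 genes of the catabolism list, 0 were higher and 4 lower with DCA (1 and 4 adjusted over the list alone; adjusted p = 0.0712).

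Of 19 chaperone genes, 1 was higher and 6 were lower with DCA than with vanillate (1 and 11 adjusted over the list alone; adjusted p = 3.47e-05, and adjusted p = 0.388 with an estimated correlation). Of 56 ribosomal protein genes, 12 were higher and 0 lower (19 and 1 adjusted over the list alone; adjusted p = 2.88e-05, and adjusted p = 0.388 with an estimated correlation). Among the 50 genes called in opposite directions, the thioredoxin gene trxA (SLG_14660), chosen after its values were seen, stood at 0.50 ± 0.11 with vanillate and -1.69 ± 0.11 with DCA, and SLG_09500 at -0.72 ± 0.11 and 1.27 ± 0.11. The vanillate call of SLG_09500 ended without vanillate replicate 1 (-0.59, adjusted p = 0.0898). That of trxA ended without vanillate replicate 1 (0.44, adjusted p = 0.188) and without vanillate replicate 2 (0.56, adjusted p = 0.127). It also ended with median centring (0.05, adjusted p = 0.866), equal scale (0.52, adjusted p = 0.0523) and 6 scans as separate channels (0.43, adjusted p = 0.109).

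In all, 411 genes differed between DCA and vanillate, 220 higher and 191 lower with DCA, and 217 by at least 2-fold (115 higher, 102 lower). The share higher with DCA was 53.5%, but 72.3% with median centring, and without DCA replicate 1 there were 117 higher and 118 lower. With the replicate number as a block, which takes in the shared control scan, the count was 843 and included 411 of the 411. With all 9 scans as separate channels it was 1591, and in the same kind of fit on the 6 scans of the hybridisation set that holds both treatments it was 1334, while the quantification day of each treatment is its own. It was 940 with replicate 3 turned as its headers say, 0 in limma with replicate 3 turned as labelled (1 at an unadjusted p under 0.05), and 147, 85, 235 and 153 without vanillate replicates 1 and 2 and DCA replicates 1 and 2 in turn.

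**Figure D3:**
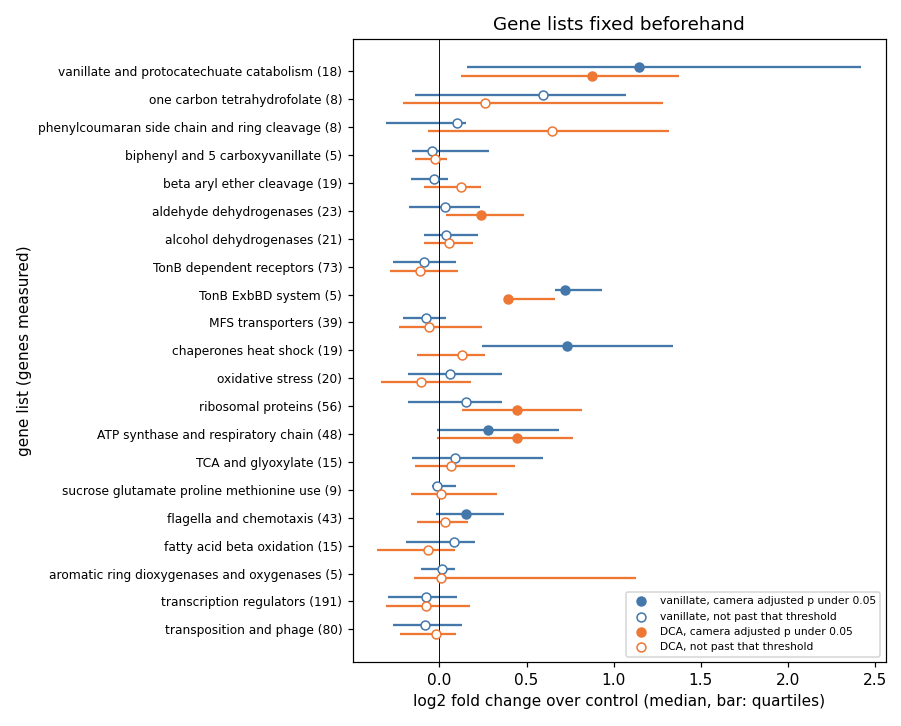
Median log2 fold change over control (x axis, bars from lower to upper quartile of the members) of the gene lists fixed beforehand (y axis), with vanillate in blue and with DCA in orange, filled where the list passed the camera threshold. The list for vanillate and protocatechuate catabolism has medians of 1.15 and 0.87, the chaperone list 0.73 and 0.13, and the ribosomal list 0.15 and 0.45.

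The remaining lists passed camera in neither treatment nor in their difference. For vanillate the camera adjusted p of these lists ran up to 0.957, the value of fatty acid oxidation, and for DCA up to 0.968, the value of biphenyl degradation. In fry, alcohol dehydrogenases, major facilitator transporters and transcription regulators passed with vanillate (adjusted p = 0.02575 each), as did beta-aryl ether cleavage (adjusted p = 0.0418). Aromatic ring dioxygenases passed fry with DCA (adjusted p = 0.0276). The one-carbon list passed fry with vanillate (adjusted p = 0.02575) and with DCA (adjusted p = 0.0276). Of 73 TonB-dependent receptor genes, 5 rose and 6 fell with vanillate (4 and 5 adjusted over the list alone) and 9 rose and 8 fell with DCA (8 and 6). Of 191 transcription regulator genes, 13 rose and 24 fell with vanillate (11 and 20 adjusted over the list alone) and 23 rose and 32 fell with DCA (24 and 33). The list for beta-aryl ether cleavage also takes in genes annotated only as glutathione S-transferase. Of its 19 genes, 0 rose and 1 fell with vanillate, and 3 rose and 1 fell with DCA, as also adjusted over the list alone. The gene that fell was gst (SLG_04120) with both treatments. With DCA ligP rose by 0.84 ± 0.09 and ligD by 0.66 ± 0.09, the latter a call that ended without DCA replicate 2 (0.69). Median and mean of the biphenyl list had opposite signs with vanillate, with DCA and in their difference. So had those of the lists for fatty acid oxidation and for use of sucrose, glutamate, proline and methionine with vanillate and in the difference. The same held for beta-aryl ether cleavage and major facilitator transporters with DCA, and for aromatic ring dioxygenases in the difference. Mean and camera direction had opposite signs for fatty acid oxidation with vanillate and for beta-aryl ether cleavage and major facilitator transporters with DCA.

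The responses to vanillate and DCA were correlated across genes, which are not independent replicates, at r = 0.55 and rho = 0.48. Unchanged groups simulated against the same control scans gave r = 0.50 (100 simulations), with a covariance of 0.0119 against 0.16 observed, a difference of 0.148. The simulation holds no difference between hybridisation sets. In both treatments 208 genes rose, against 76.4 for independent lists, and 222 fell, against 58.3, while 50 were called in opposite directions, for which no such value was computed. Both lists rest on the same control scans, so independent lists are not the no-change case. No overlap under shared controls was simulated. Ratios against the same control scan correlated at 0.56 and 0.52 and ratios against different ones at 0.47, so part of the excess may come from the shared controls. All these ratios set treated scans against control scans of another hybridisation set. A set effect would enter both responses alike, and it cannot be told apart here from a response common to both treatments.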

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

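The tests of replicate 3, of single scans, of quantification day and of hybridisation set were chosen only after the results were seen; those of neighbouring spots were set before their values were seen.

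Replicate 3 of both groups, which the fits leave out, carried a clear signal. Turned as its headers say, its lowest correlation with the other replicates was 0.778 for vanillate and 0.854 for DCA, and turned as labelled the same values are negative. With replicates 1 and 2 of the other treatment, replicate 3 turned by its headers correlated at 0.418 and 0.444 for vanillate and 0.499 and 0.468 for DCA. All treated scans share a hybridisation set, so a correlation above 0 alone does not show a signal of the treatment. Scans without such a signal are argued against by the higher values within each group, the smallest being 0.778. That the dye labels hold in both groups is ruled out, since in 2 groups the file labelled as treated is the same scan. Wrong dye labels are a likely explanation: the DCA minus vanillate difference between the files labelled as control correlated across genes with that of the treated scans of replicates 1 and 2 at r = 0.823, where a pair of control scans would differ by neither treatment. Quantification day goes with treatment in this test too, and where the error arose was not tested.

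Genes from SLG_38200 to SLG_38400, which include the cbb3 oxidase genes, were higher with vanillate than with DCA. Of the 21 genes 12 rose and 1 fell with vanillate, 6 rose and 0 fell with DCA, and 9 were lower in DCA minus vanillate. A local artifact on the slides is argued against by the 111 spots printed next to them, whose median difference was 0.0892, and 1 aberrant vanillate scan by the lowest vanillate median of the stretch, which lies 0.436 above the highest DCA median. The quantification day stays open, since 0 groups have scans on both days, so day and treatment cannot be told apart. The treatments, with their different times, remain untested as a possible explanation.

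With both treatments metE, SLG_27180, SLG_27190, SLG_36750, SLG_36760 and SLG_10570 were far lower than in the control. Against each of the 3 control scans their median log2 ratio was -3.37 or lower, which argues against 1 aberrant control scan, and the 50 gene spots printed next to theirs had medians of -0.0406 with vanillate and -0.0135 with DCA, close to 0, which argues against a local artifact. The hybridisation set stays open, since 0 groups have scans in both sets and set and treatment cannot be told apart. That the substrates themselves lower these genes may hold, untested apart from the set.

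Other results stood out because the responses to DCA and vanillate differed in a test of the difference. For single genes it was 3.98 for SLG_38040, 3.36 for SLG_38050, 3.16 for SLG_09380, 3.04 for SLG_38070, 3.00 for SLG_35980, -3.15 for SS1C_Con002_0044, -3.05 for ccoP, -2.72 for SLG_38360, -2.62 for SLG_38320 and -2.61 for SLG_37520, on the log2 scale. Without vanillate replicate 2 the calls of ccoP (-2.80, adjusted p = 0.0592), SLG_37520 (-2.32, adjusted p = 0.0724) and SLG_38360 (-2.72, adjusted p = 0.0637) ended, the last also without vanillate replicate 1 (-2.71, adjusted p = 0.0583). Called in opposite directions by the 2 treatments were 50 genes, among them SLG_09380 (-1.12 with vanillate, 2.04 with DCA), SLG_35980 (-2.24 and 0.76), SLG_09500 with a difference of 1.99, trxA with -2.19 and fliC with -0.93. The DCA call of SLG_35980 ended without DCA replicate 2 (0.41, adjusted p = 0.242) and with median centring (0.77, adjusted p = 0.0528). The differences of SLG_09500, trxA and fliC lie outside the rule for named genes and were chosen after values were seen. The same holds for the values of SLG_09380 and SLG_35980 with each treatment. The vanillate call of fliC (0.52) ended with median centring (0.35, adjusted p = 0.119) and without vanillate replicate 1 or 2 (0.49, adjusted p = 0.117, and 0.56, adjusted p = 0.0936). Its DCA call (-0.41) ended with median centring (-0.44, adjusted p = 0.0584) and without DCA replicate 1 or 2 (-0.42, adjusted p = 0.129, and -0.41, adjusted p = 0.182). Its difference missed the threshold without vanillate replicate 1 or 2 (-0.90, adjusted p = 0.0755, and -0.97, adjusted p = 0.0724) and without DCA replicate 1 or 2 (-0.94, adjusted p = 0.0539, and -0.93, adjusted p = 0.0656). The vanillate call of SLG_09500 (-0.72) ended without vanillate replicate 1 (-0.59, adjusted p = 0.0898). That of trxA (0.50) ended with median centring, where 0.05 was left (adjusted p = 0.866), with equal scale (0.52, adjusted p = 0.0523), with 6 scans (0.43, adjusted p = 0.109) and without vanillate replicate 1 or 2 (0.44, adjusted p = 0.188, and 0.56, adjusted p = 0.127). Against all other genes, the chaperone list differed by -0.70 (adjusted p = 3.47e-05) and the ribosomal list by 0.34 (adjusted p = 2.88e-05), both lost with an estimated correlation (adjusted p = 0.388).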

How the results depend on the processing

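The fits of 9 scans as separate channels, of 1 quantification day, of 1 hybridisation set, of the block with replicate 3 and of different control scans were chosen only after the data were seen, as were the splits. No named gene call, list call or correlation reversed under any alternative run, but the side with more calls did. Against 492 higher and 469 lower, vanillate gave 318 and 605 with median centring, 740 and 838 with replicate 3 turned as its headers say, 561 and 654 with 6 scans and 787 and 936 with 9; against 668 and 534, DCA gave 636 and 657 with 6 scans, 758 and 806 with 9 and 927 and 993 within 1 quantification day; and against 220 and 191 the difference gave 117 and 118 without DCA replicate 1. Gene counts within 1.5 times of the reported ones came from no background correction, median centring, equal scale, the filter on dim genes, the median of spots, groups fitted alone and the deposited processed values (1022, 1309 and 274 spots). With replicate 3 turned as its headers say, vanillate gave 1578 genes and the difference 940; turned as labelled, all 3 comparisons gave 0 in limma (12, 22 and 1 at an unadjusted p under 0.05), as opposed ratios cancel, and DCA gave 2 lists. With 9 scans vanillate gave 1723 and the difference 1591, and with 6 scans as separate channels the difference gave 1202. Separate channels within 1 quantification day gave 1920 for DCA (1564 with 9 scans), still across hybridisation sets. Within 1 hybridisation set they gave 1334 for the difference, still across quantification days. The cause of these changes was not tested. The replicate block gave 843, and 1298 with replicate 3, and in the difference, for which alone the block was run, changed no list's call. Leaving out each replicate gave 277 to 958 genes for vanillate, 369 to 1057 for DCA and 85 to 235 for the difference, with 1 residual degree of freedom and the lone array assumed to vary like the other group; the difference then had 2 to 5 lists. With an estimated correlation 0 lists passed in camera (2, 1 and 2 at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, gave 10, 7 and 3. That form of camera tests on the 2 residual degrees of freedom, so few lists could pass whatever their correlation. For the ribosomal list with DCA the estimated correlation was -0.0175, yet the camera p went from 2.26e-08 to 0.02004. For the TonB-ExbB-ExbD and flagellar lists the estimated correlation was 0.708 and 0.268, so correlation may have added to the loss of their calls. The difference had 4 lists with median centring and 5 with equal scale; the cause was not tested. Similarity was 0.47 against different control scans, which removes the shared scan but not the hybridisation set of the controls. Of 197 named gene values, 177 kept their side of the threshold with median centring, 191 with the header direction and 189 with 9 scans, where 4 and 8 became calls, and leaving out vanillate replicate 2 ended 37. Of the 10 splits of the 6 scans of each comparison, 1 (the real one) gave as many genes, with 1723, 1564 and 1591 against at most 0 in the others in limma (198, 92 and 235 at an unadjusted p under 0.05). These 10 splits are too few for a share under 0.05. Every other split mixes the groups, so group differences widen its spread and a low count was to be foreseen. The real split also follows hybridisation set against control, or quantification day between treatments, so it cannot separate treatment from batch. A dye term and a scan block were not run, since no swapped scan is in the fit and batches follow the groups; groups fitted alone give no difference, and unnamed rows no gene values. Equal scale stands for the between-array option that leaves log ratios as they are. Signal over background limits dim genes most in vanillate replicate 3, with a median signal of 74.5.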

Other observations

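The gene groups and tests here were chosen after the results were seen, except the test of neighbouring spots. Beyond the fixed lists, several runs of neighbouring loci changed together. The 10 genes from SLG_38030 to SLG_38120 had a median log2 change of 1.90 with DCA and -0.02 with vanillate; they include a transporter gene (SLG_38030), the receptor gene SLG_38050 and the putative FAD-linked oxidase gene SLG_38080, which rose by 2.10 ± 0.11. The 6 genes from SLG_12890 to SLG_12940, with the subunits of an NAD-dependent formate dehydrogenase, rose with both treatments, with medians of 1.81 for vanillate and 2.21 for DCA. With DCA the efflux genes SLG_34610, SLG_34620 and SLG_34630 rose by 1.73 ± 0.18, 2.07 ± 0.16 and 2.90 ± 0.19, where vanillate gave -0.25, 0.24 and 0.62, none past the threshold. The value of SLG_34630 with vanillate passed without vanillate replicate 2 (0.98, adjusted p = 0.049) and with 6 and 9 scans (0.60, adjusted p = 0.0385, and 0.42, adjusted p = 0.0386).

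The 7 neighbouring genes from SLG_32260 to SLG_32320 were lower with DCA, with a median of -2.14, among them the sulfite reductase gene SLG_32290 at -2.74 ± 0.10 and cysH, a phosphoadenosine phosphosulfate reductase gene, at -2.32 ± 0.11. With vanillate the 5 genes from SLG_32280 to SLG_32320 were called lower as well, SLG_32290 at -1.65 ± 0.10 and cysH at -1.33 ± 0.11. With vanillate, the 7 genes from SLG_34500 to SLG_34560, which include the receptor gene SLG_34550, had a median of -1.08, and with DCA one of -0.87.

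Runs of at least 5 neighbouring loci called in the same direction numbered 9 with vanillate and 11 with DCA, against at most 2 and 3 in 1000 shuffled orders. Shared transcription units along the chromosome are a candidate explanation: the change of a locus correlated with that of the next at r = 0.336 with vanillate and 0.347 with DCA, above the highest shuffled values of 0.0512 and 0.0484. Neighbouring spots on the slides are argued against as the source, since with vanillate and with DCA spots printed side by side correlated at no more than 0.0901. For DCA minus vanillate the value was 0.134, against 0.31 for neighbouring loci.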
